A study of Mus musculus with 42 samples.

How the data were processed

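RNA-seq of mouse cells on the way from embryonic fibroblasts to induced pluripotent stem cells (iPSC) was analysed in 42 libraries of 14 groups, 3 per group, in 2 batches of 21. The nx2 set (3 lines with a Tet1-mCherry and a Pou5f1-EGFP transgene, batch 1) holds fibroblasts (MEF), cells sorted at days 10, 12 and 14 for mCherry with or without GFP, and iPSC. The tx2 set (3 lines with reporters at Tet1 and Pou5f1 themselves, batch 2) holds cells sorted at days 8, 10 and 12. Batch 2 also holds iPSC clones of wild-type and Tet1 knockout mice. Group, day, line and stage come from the labels, which give every library as male. The title of replicate 2 of the tx2 day 12 mCherry+/GFP- cells lacks the mCherry mark of the others, so its gate rests on its source name alone. Per the labels' protocols the libraries are stranded and made from poly(A) RNA, and iPSC were passaged on feeders and then depleted of them.

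The deposited values are raw counts per gene name, made by the authors with featureCounts 1.5.3 over the whole gene body, introns included, on the reverse strand (setting 2), per the file headers. No option for reads shared between genes is in the headers, so a read in more than 1 gene on the same strand was not counted. Alignment to mm10 was by HISAT2 2.1.0 and the authors' own testing by DESeq2 1.18.1, per the submitters' processing notes. Both tables hold 48321 names, and 0 columns lacked a sample in the labels. Counts summed to 6540256 to 20783265 per library and came from 18838 to 21666 genes, with 1.753 to 12.18% on mitochondrially encoded genes. The fold against a group with 0 counts is given as a bound at a floor of 3 counts per library, which is 0.183 to 0.444 CPM by group.

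All choices of groups, comparisons, gene lists, tests, named genes and alternatives were made before the data were examined, apart from those named as added later. Counts were filtered with filterByExpr, scaled by TMM (factors 0.7818 to 1.07) and tested with edgeR 4.0.16 quasi-likelihood F tests with robust dispersion in R 4.3.3, within a batch for 12 comparisons of groups. The 4 comparisons of differences (GFP effects between days or between systems, and stage III through the iPSC of each batch) are contrasts of 4 groups. Those across systems use a joint fit of all 42 libraries. P values were adjusted by Benjamini-Hochberg and called at 0.05. Values are mean ± SD of CPM over 3 libraries, and log2 fold change ± standard error. CPM uses the TMM-scaled totals and log2 levels a prior count of 2. The 28 gene lists of known markers were tested, where at least 5 members were tested, by camera on voom values (limma 3.58.1) with an inter-gene correlation of 0.01, and again with the correlation estimated. Counts of called members use the adjustment over all genes, and where stated over the list alone.

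Named genes follow a rule. They are the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap of the libraries, predicted and clone names left out, and without the CPM and overlap terms for differences. To these come up to 4 called members of each called list with the smallest p and 1 against its direction, and Tet1, Tet2, Tet3, Pou5f1, Nanog, Sox2, Zfp42, Esrrb, Dppa3, Dnmt3a, Dnmt3b, Dnmt3l, Cdh1, Col1a1 and Thy1. Not every gene under the rule is described, and some are not reported here. Sox2 has 0 counts in all libraries and was not tested.

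Replicate numbers are lines in nx2 and tx2, which pairs the libraries, and clone numbers in the iPSC of batch 2. Deviations from the group mean of same-line libraries correlated at 0.126 to 0.593 in tx2 (all 30 pairs over 0.1) and at -0.121 to 0.359 in nx2 (31 of 63 over 0.1). The alternatives were RLE size factors, library totals alone, no low-count filter, at least 1 CPM in 3 libraries, only the groups of the contrast, a replicate block, DESeq2 1.42.0, each library left out in turn, and, added later, leaving out the 2 libraries with over 8% mitochondrial reads. Gene overlaps were found with GenomicRanges 1.54.1 on the gene spans deposited with the counts. Which names are protein-coding was taken from a later GENCODE release than that of the counts. Figures were drawn with matplotlib 3.10.9.

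The test was run on simulated counts, which need not vary as real libraries do. In nx2 day 12 GFP+ against GFP- cells it called 41.8% of 1.5-fold, 68.7% of 2-fold and 80.3% of 4-fold changes, and 5 of 15716 unchanged genes. In knockout against wild-type iPSC the shares were 20.9, 70.1 and 87.9%, and in the difference of GFP effects between systems at day 12 they were 19.4, 44.8 and 75.8%.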

Results

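Tet1, which encodes a dioxygenase that oxidises 5-methylcytosine, fell in the knockout clones. The 3 Tet1 knockout iPSC clones held 54.4, 58.6 and 57.3 CPM of Tet1 against 1303, 823 and 874 CPM in the 3 wild-type clones, a log2 fold change of -4.14 ± 0.18 (adjusted p = 2.5e-11). Reads are counted over the whole gene body, parts outside the disrupted region included. Its relatives were not called in the knockout: Tet2 was at 307 ± 18.3 against 346 ± 153 CPM (adjusted p = 0.594) and Tet3 at 19.4 ± 1.63 against 16.7 ± 2.22 CPM (adjusted p = 0.272).

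Along reprogramming the 3 family members moved apart. In the nx2 lines (a Tet1-mCherry transgene with a Pou5f1-EGFP transgene) Tet1 went from 10.3 ± 1.59 CPM in fibroblasts (MEF) to 755 ± 66.6 CPM in mCherry+ cells at day 10 and 1025 ± 205 CPM in iPSC. Over the same groups Tet2 went from 28.7 ± 1.74 to 445 ± 79.1 and 294 ± 30.0 CPM. Tet3, the form of the oocyte and of differentiated cells, went the other way, from 127 ± 6.13 to 16.5 ± 1.59 and 25.2 ± 3.00 CPM. In the tx2 lines (mCherry at Tet1 itself and GFP at Pou5f1 itself, by strain name) mCherry+/GFP- cells at day 8 held Tet1 at 95.1 ± 11.1 and Tet3 at 93.4 ± 7.72 CPM. Day 12 mCherry+/GFP+ cells held 518 ± 17 and 24.8 ± 1.80 CPM.

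**Figure D1:**
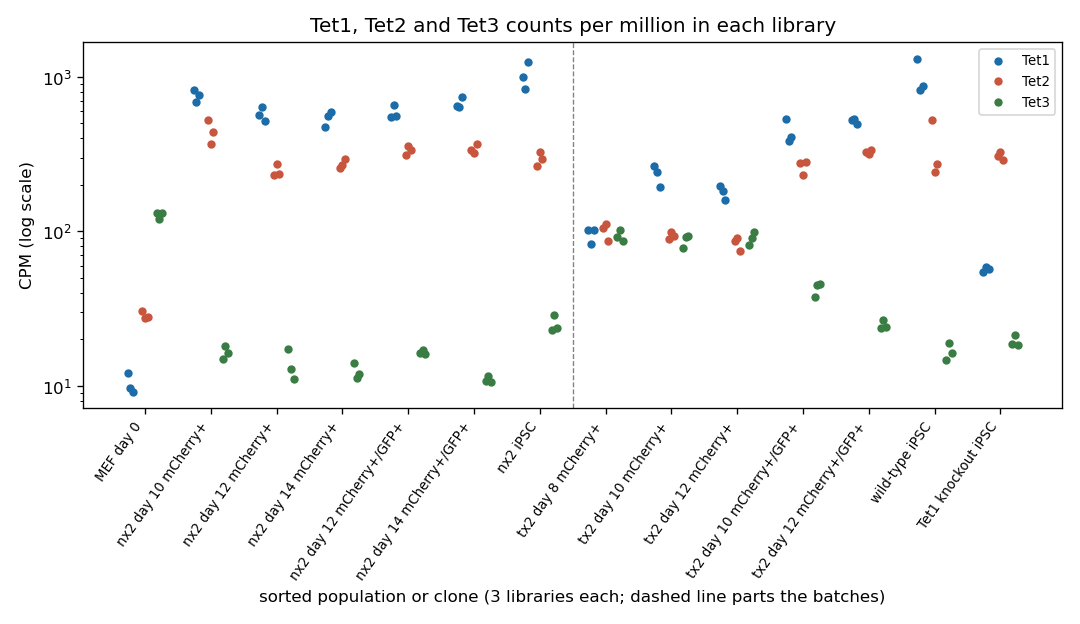
CPM (log axis) of Tet1, Tet2 and Tet3 in each of the 3 libraries of every sorted population or clone group, a point per library, with a dashed line between the batches, which were normalised apart. Tet1 and Tet2 sit low in MEF and high in nx2 iPSC, Tet3 the other way round, and the Tet1 points of the knockout clones lie between 54.4 and 58.6 CPM.

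Col1a1, a fibrillar collagen, fell from 8697 ± 293 CPM in MEF to 282 ± 61.2 CPM in day 10 mCherry+ nx2 cells (log2 fold change -4.95 ± 0.42, n = 3 and 3). Vim, the mesenchymal intermediate filament, fell from 6065 ± 196 to 119 ± 20.6 CPM. Twist2, a mesenchymal transcription factor, fell by 7.71 ± 0.34 log2 units, and Thy1, a fibroblast surface marker, fell by 3.94 ± 0.33. Of 30 fibroblast and mesenchymal genes 28 were lower and 0 higher (median log2 fold change -4.48, camera adjusted p = 6.8e-10), with 28 when adjusted over the list alone. Here and below p_e is the adjusted p of the same list test with an estimated correlation, 0.243 for this list. All 19 tested TGF-beta and activin response genes were lower, Inhba (-10.50 ± 0.74) and Id1 (-4.82 ± 0.26) among them (adjusted p = 4.6e-08, p_e = 0.124). Muscle genes were lower in 11 of 12 cases, with Acta1 at -7.93 ± 0.60 (adjusted p = 0.00143, p_e = 0.133). Leukocyte genes were lower in 12 of 14, with Csf1r, the macrophage growth factor receptor, at -6.50 ± 0.41 (adjusted p = 0.0129, p_e = 0.26).

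Over the same step Pou5f1, Nanog and Sall4, core factors of the pluripotent state, rose to 666 ± 159, 535 ± 99.3 and 316 ± 28.3 CPM from 1.14, 0.45 and 0.17 CPM. Counts per gene name do not part endogenous transcripts from those of any delivered reprogramming factors, here and wherever Pou5f1, Myc or Klf4 is given. Dppa4, a chromatin factor of pluripotent cells, rose from 0 counts in MEF by at least 136-fold. All 19 shared pluripotency genes were higher (median 9.54, or 9.16 with genes at 0 set to their bound; adjusted p = 6.8e-10, p_e = 0.0231). Of 22 naive genes 18 were higher (adjusted p = 1.5e-05, p_e = 0.116). Esrrb was at 578 ± 69.0 CPM and Tfcp2l1, both naive-state transcription factors, at 451 ± 71.0 CPM. Zfp42 (Rex1), a late marker of the naive state, was still at 17.3 ± 4.09 CPM. Epithelial genes rose in 20 of 22 cases (adjusted p = 2.4e-06, p_e = 0.0923). The adhesion genes Epcam and Cdh1 rose by 9.44 ± 0.14 and 8.38 ± 0.15, while Krt19 fell by 4.23 ± 0.24. Other genes rose from 0 counts in MEF, such as Trh, thyrotropin-releasing hormone (at least 611-fold), the tight-junction gene Tjp3 (at least 369-fold) and the epithelial factor Elf3 (at least 209-fold).

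Of 16 genes of DNA methylation and demethylation 12 were higher and 3 lower (adjusted p = 0.00195, p_e = 0.0344). The de novo methyltransferase Dnmt3b rose by 5.25 ± 0.12 and its cofactor Dnmt3l by 6.29 ± 0.45, while Dnmt3a fell by 0.70 ± 0.11. Polycomb repressive complex 2 genes were higher in 8 of 12 cases (adjusted p = 0.00709, p_e = 0.0923). The cofactor Jarid2 rose by 3.89 ± 0.08 and the catalytic Ezh2 by 1.27 ± 0.07. All 22 cell division genes were higher (adjusted p = 1.1e-07, p_e = 0.174). The replication helicase gene Mcm2 rose by 1.49 ± 0.07. Oxidative phosphorylation genes were higher in 18 of 25 cases (adjusted p = 0.0214, p_e = 0.46). Imprinted genes were lower in 23 of 30 cases (adjusted p = 0.000663, p_e = 0.243). Igf2r, the scavenger receptor of IGF2, fell by 1.80 ± 0.08. Germline genes were higher in 18 of 26 cases (adjusted p = 0.0251, p_e = 0.252, and 0.0858 without the day 10 library of 8.99% mitochondrial reads). The piRNA factor Piwil2 rose by 6.59 ± 0.28. Endoderm genes were lower in 9 of 13 cases (adjusted p = 0.0251, p_e = 0.133), with Col4a1 at -4.35 ± 0.24. Stress genes were lower in 14 of 19 (adjusted p = 0.0209, p_e = 0.243), such as Dusp1 (-3.09 ± 0.16). In all 12319 of 16132 tested genes changed, 6261 up and 6058 down. With library totals alone the median of all genes moved from 0.06 to 0.34 log2 units.

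From day 10 to day 14 Myc, a proto-oncogene and a reprogramming factor, fell in the mCherry+/GFP- nx2 cells from 448 ± 27.5 to 10.2 ± 1.82 CPM (log2 fold change -5.46 ± 0.25, n = 3 and 3). Rapgef4, a cAMP-activated exchange factor, fell from 61.8 ± 3.69 to 2.33 ± 0.59 CPM, and Trh from 154 ± 15.3 to 13.7 ± 4.22 CPM. Krt7, Gata2 and Gata3, genes of the trophectoderm lineage, rose by 4.02 ± 0.29, 2.90 ± 0.24 and 2.63 ± 0.28. Of 14 trophectoderm genes 8 were higher and 2 lower (adjusted p = 0.00505, p_e = 0.221), with 10 higher and 2 lower over the list alone. Tead4, a trophectoderm factor also present in naive cells, was lower (-0.94 ± 0.07).

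The naive list had 13 of 22 higher (adjusted p = 0.00416, p_e = 0.288), with Tbx3 at 107 ± 2.82 against 32.4 ± 5.64 CPM and Zfp42 at 41.2 ± 3.39 against 17.3 ± 4.09 CPM. The germline list had 15 of 26 higher (adjusted p = 0.000493, p_e = 0.247), with Hormad1, a meiotic chromosome axis gene, up by 2.51 ± 0.33. Dnmt3l rose from 22.8 ± 6.01 to 130.4 ± 17.5 CPM and Nanog from 535 ± 99.3 to 729 ± 23.6 CPM. Pou5f1 and Esrrb were not called (adjusted p = 0.608 and 0.382), though Pou5f1 fell by 0.29 without the library of high mitochondrial share (adjusted p = 0.00817). Cdh1 fell by 0.44 ± 0.10.

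Of 30 fibroblast and mesenchymal genes 22 were higher and 0 lower (median 1.35, adjusted p = 6.1e-07, p_e = 0.344). Col1a1 went from 282 ± 61.2 to 1462 ± 399 CPM, with MEF at 8697 ± 293 CPM, and Tagln, a smooth-muscle actin-binding gene, from 6.24 ± 0.28 to 56.5 ± 9.58 CPM. TGF-beta and activin response genes were higher in 13 of 19 cases (adjusted p = 0.000493, p_e = 0.302). Bmp4 rose by 1.75 ± 0.20. Muscle genes were higher in 7 of 12 cases (adjusted p = 0.00788, p_e = 0.278), with Des up by 1.36 ± 0.14. Of 19 stress genes 10 were higher (adjusted p = 0.00416, p_e = 0.269), with Dusp1 up by 1.12 ± 0.16. The p53 and senescence genes had 8 of 19 higher (adjusted p = 0.0442, p_e = 0.344), with the cell-cycle inhibitor gene Cdkn2b up by 1.5 ± 0.29. The p53 call was lost without the day 10 library of high mitochondrial share (adjusted p = 0.0516). That library also made the fall of the mitochondrially encoded genes, 4 of 9 lower with it (adjusted p = 0.0442, p_e = 0.525) and adjusted p = 0.588 without it. In all 5934 of 16132 genes changed, 3280 up and 2654 down, and 4043 up and 1830 down with library totals alone.

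At day 12 in nx2 Rpl10l, a ribosomal protein gene of the testis, was at 23.2 ± 2.63 CPM in mCherry+/GFP+ against 0.64 ± 0.47 CPM in mCherry+/GFP- cells (log2 fold change 5.06 ± 0.36, n = 3 and 3). Tuba3a, a testis tubulin, was at 17.7 ± 3.89 against 0.69 ± 0.21 CPM, and Dazl, an RNA-binding regulator of germ cells, at 13.1 ± 0.91 against 1.01 ± 0.18 CPM. Of 26 germline genes 20 were higher and 1, the X-linked Rhox9 (-1.26 ± 0.21), lower (median 2.21, adjusted p = 3.3e-14, p_e = 0.00316). The meiotic genes Hormad1 and Fkbp6 rose by 2.95 ± 0.29 and 2.94 ± 0.28. Outside the list, Galnt6, a glycosyltransferase gene, rose to 48.4 ± 9.65 from 3.51 ± 1.32 CPM. The embryonic stem cell transcript Lncenc1 rose to 81.3 ± 23.1 from 6.08 ± 2.04 CPM and the Y-linked Usp9y to 16.1 ± 2.56 from 1.54 ± 0.86 CPM.

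Naive genes were higher in 11 of 22 cases and lower in 1, and in 14 and 2 over the list alone (adjusted p = 8e-07, p_e = 0.0768). Tbx3 rose from 46.1 ± 6.49 to 204 ± 15.1 CPM and Zfp42 from 23.2 ± 2.46 to 84.2 ± 9.40 CPM. Dppa3, an oocyte and naive-state gene, fell from 51.3 ± 6.41 to 37.1 ± 4.56 CPM, a call lost when any of 3 libraries was left out (adjusted p up to 0.0909). Shared pluripotency genes were higher in 8 of 19 cases (adjusted p = 0.00409, p_e = 0.212). Dppa4 rose by 1.08 ± 0.08. Pou5f1 (772 ± 38.7 against 662 ± 33.6 CPM), Nanog and Tet1 (adjusted p = 0.25, 0.594 and 0.902) were not called, though Pou5f1 was with only the groups of the contrast in the fit (0.0144) and without the library of high mitochondrial share (0.0385). Dnmt3l rose by 1.01 ± 0.23 and Dnmt3a fell by 0.55 ± 0.12.

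Of 22 epithelial genes 8 were lower and 1 higher, and 11 and 1 over the list alone (adjusted p = 9.5e-06, p_e = 0.0975). Krt18 fell by 1.34 ± 0.21, Krt8 by 1.16 ± 0.24 and Cldn3 by 1.12 ± 0.17, while Grhl2, an epithelial transcription factor, rose by 1.04 ± 0.22. Trophectoderm genes were lower in 6 of 14 cases (adjusted p = 0.00558, p_e = 0.0768), with Tfap2c from 220 ± 10.7 to 109 ± 3.60 CPM. Of 30 imprinted genes 11 were lower and 3 higher (adjusted p = 0.00122, p_e = 0.303). H19, a growth-restraining noncoding RNA, fell by 1.66 ± 0.36, Peg10, a placental retrotransposon-derived gene, by 1.52 ± 0.22, and Slc38a4 rose by 0.91 ± 0.09. Stress genes were lower in 6 of 19 cases (adjusted p = 0.00631, p_e = 0.212), with Egr1 down by 0.84 ± 0.17. In all 2681 genes changed, 1602 up and 1079 down.

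At day 14 in nx2 Dazl reached 42.4 ± 3.65 CPM in mCherry+/GFP+ against 1.67 ± 0.16 CPM in mCherry+/GFP- cells (log2 fold change 4.66 ± 0.33, n = 3 and 3). Rpl10l reached 32.3 ± 2.52 against 1.03 ± 0.12 CPM, and Sohlh2, a transcription factor of spermatogonia, 14.9 ± 0.44 against 0.37 ± 0.15 CPM. Of 26 germline genes 18 were higher and 2 lower (median 1.72, adjusted p = 4.6e-08, p_e = 0.0191), the cohesin gene of meiosis Smc1b among them (3.03 ± 0.27). The largest rise was of A2m, a protease inhibitor gene, to 32.0 ± 3.02 from 0.60 ± 0.32 CPM, followed by Sohlh2 and Nphs1, a gene of the kidney slit diaphragm (5.19 ± 0.54).

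Of 14 trophectoderm genes 10 were lower and 1 higher (median -1.55, adjusted p = 0.000102, p_e = 0.0191). Krt7 fell by 2.47 ± 0.25 and Hand1 by 3.15 ± 0.41. Nrk, a kinase gene of the placenta, went from 53.6 ± 3.23 to 5.86 ± 0.35 CPM. The X-linked homeobox genes Rhox6 and Rhox9 fell by 3.13 ± 0.20 and 3.11 ± 0.22, and Plac1 fell by 3.93 ± 0.33. Epithelial genes were lower in 15 of 22 cases (adjusted p = 2.2e-06, p_e = 0.0723). Krt8 went from 90.5 ± 16.1 to 13.8 ± 3.57 CPM and Krt18 fell by 2.51 ± 0.20. Keratinocyte-like genes were lower in 7 of 11 cases (adjusted p = 0.00728, p_e = 0.122), with Perp, a desmosome gene, down by 1.13 ± 0.19.

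Of 30 imprinted genes 16 were lower and 1 higher (median -0.73, adjusted p = 4.3e-06, p_e = 0.122). H19 went from 776 ± 93.7 to 91.8 ± 11.4 CPM, its neighbour Igf2, a fetal growth factor, from 192 ± 39.3 to 24.7 ± 4.58 CPM. Peg10 went from 537 ± 80.2 to 105 ± 17.7 CPM and Cdkn1c, a cell-cycle inhibitor gene, from 50.9 ± 6.24 to 10.3 ± 0.22 CPM. The exception was Zdbf2, which rose from 9.28 ± 0.70 to 66.9 ± 4.56 CPM.

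Naive genes were higher in 13 of 22 cases and lower in 1 (adjusted p = 8.2e-06, p_e = 0.1). Tbx3 reached 271 ± 9.89 CPM, Zfp42 109 ± 6.73 CPM and Tcl1, an AKT coactivator gene, 56.3 ± 7.98 CPM, while Dppa3 fell by 1.17 ± 0.13. Shared pluripotency genes were higher in 12 of 19 (adjusted p = 2.3e-06, p_e = 0.0506). Lin28a, a let-7 inhibitor gene, rose by 1.06 ± 0.14 and Pou5f1 by 0.48 ± 0.12, and Nanog was not called (adjusted p = 0.895). Glycolysis genes were higher in 8 of 18 (adjusted p = 0.000858, p_e = 0.462). Pfkp was at 442 ± 17 against 156 ± 24.1 CPM and Hk2 rose by 0.81 ± 0.08. Fibroblast genes were lower in 15 of 30 cases, and in 23 over the list alone (adjusted p = 2.6e-05, p_e = 0.51). Thy1 fell by 1.45 ± 0.32, Pdgfrb by 1.72 ± 0.30 and Fn1 rose by 0.41 ± 0.09. TGF-beta and activin response genes were lower in 8 of 19 cases (adjusted p = 0.00382, p_e = 0.462), with Id2 down by 1.19 ± 0.15. Of 19 stress genes 7 were lower (adjusted p = 0.0411, p_e = 0.38), with Junb down by 0.91 ± 0.13. The stress call was lost under the stricter low-count filter (adjusted p = 0.0507). The 2-cell-like call (2 of 6 higher, adjusted p = 0.00791, p_e = 0.293) rests on traces. Zscan4d was at 0.45 ± 0.29 CPM and 0 in GFP- cells. In all 5056 genes changed, 2329 up and 2727 down.

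Between day 12 and day 14 Myc went in the mCherry+/GFP+ nx2 cells from 305 ± 50.1 to 7.90 ± 1.48 CPM (log2 fold change -5.28 ± 0.26, n = 3 and 3). Chac1, a glutathione-degrading gene of the integrated stress response, fell from 27.3 ± 1.17 to 2.38 ± 0.35 CPM. Nupr1, a stress-induced chromatin gene, fell from 78.7 ± 5.49 to 7.49 ± 0.61 CPM and Hrk, a pro-apoptotic BCL2-family gene, from 23.2 ± 2.44 to 1.95 ± 0.61 CPM. The largest rises were of Lef1, a WNT effector, from 1.12 ± 0.44 to 17.9 ± 4.71 CPM, of A2m (3.74 ± 0.25) and of Notum, a WNT feedback inhibitor gene (3.18 ± 0.33).

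Of 19 shared pluripotency genes 15 were higher and 0 lower (median 0.80, adjusted p = 1.7e-12, p_e = 0.0042). Utf1, a chromatin factor of pluripotent cells, rose by 0.99 ± 0.09 and Nanog from 470 ± 35.2 to 718 ± 18.7 CPM. Pou5f1 and Tet1 were not called (adjusted p = 0.306 and 0.276), but were with only the groups of the contrast (0.0243 and 0.0416). Formative and primed genes were higher in 13 of 19 cases and lower in 1 (median 0.73, adjusted p = 1.0e-06, p_e = 0.0042). The ERK target Etv4 rose by 2.03 ± 0.17, Nodal by 1.36 ± 0.15 and Dnmt3b by 0.90 ± 0.09, and Pou3f1 (Oct6), a factor of the formative state, fell by 0.81 ± 0.24, a call lost without either of 2 libraries (adjusted p = 0.0547 and 0.0543). Genes of DNA methylation and demethylation were higher in 6 of 16 (adjusted p = 0.0112, p_e = 0.0684), with Dnmt3l from 59.6 ± 10.5 to 231 ± 14.9 CPM. Naive genes were mixed, 9 of 22 higher and 3 lower (adjusted p = 0.0322, p_e = 0.412). Gbx2 rose by 2.52 ± 0.25 and Mybl2 fell by 0.37 ± 0.08.

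Glycolysis genes were higher in 13 of 18 cases, and in 16 over the list alone (adjusted p = 5.6e-09, p_e = 0.207). The glucose transporter gene Slc2a1 went from 91.3 ± 7.56 to 350.3 ± 37.5 CPM. Cell division genes were higher in 8 of 22 cases (adjusted p = 0.000451, p_e = 0.412), with Mcm5 up by 0.37 ± 0.07. Of 19 TGF-beta and activin response genes 9 were higher (adjusted p = 0.000451, p_e = 0.362). Id3, a BMP target, rose by 2.64 ± 0.26 and Bmp4 by 2.56 ± 0.23. Stress genes, 9 of 19 higher (adjusted p = 0.000451, p_e = 0.156), were led by the chaperone gene Hspa8 (1.02 ± 0.10). Fibroblast genes were higher in 13 of 30 cases (adjusted p = 0.000451, p_e = 0.504), with Col1a1 from 227 ± 92.9 to 724 ± 190 CPM. Of 12 muscle genes 5 were higher (adjusted p = 0.0111, p_e = 0.273), with Ttn up by 2.08 ± 0.43. Mesoderm genes had 5 of 10 higher, with Eomes up by 1.95 ± 0.27, and interferon genes 5 of 20, with Oas1a up by 2.08 ± 0.39. Both were at the threshold (adjusted p = 0.0477 each, p_e = 0.163 and 0.542) and lost under RLE scaling (adjusted p = 0.0605 each). In all 4919 genes changed, 2344 up and 2575 down.

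From day 14 mCherry+/GFP+ nx2 cells to nx2 iPSC Clec2g and Clec2i, C-type lectin genes, fell from 37.4 ± 1.46 and 48.0 ± 4.10 CPM to 0.04 ± 0.07 and 0.28 ± 0.13 CPM. Trpm2, an oxidant-gated cation channel gene, fell from 22.3 ± 5.69 CPM to 0 (at least 105-fold), and Arntl2, a clock gene, from 209 ± 10.7 to 5.23 ± 2.44 CPM (log2 fold change -5.30 ± 0.19, n = 3 and 3). Dppa3 fell from 43.8 ± 4.74 to 4.23 ± 0.90 CPM, Nanog by 0.66 ± 0.10 and Zfp42 by 0.35 ± 0.12. Pou5f1 and Esrrb were not called (adjusted p = 0.0797 and 0.457). Without iPSC replicate 2 Pou5f1 fell by 0.36 (adjusted p = 0.0356), and it was called with only the groups of the contrast (0.0321). The Zfp42 call was lost without either of 2 libraries (0.0629 and 0.0973). Dnmt3a rose from 70.2 ± 6.93 to 240 ± 45.6 CPM, Tet3 by 1.20 ± 0.13 and Tet1 by 0.61 ± 0.13. Neither the shared, the naive nor the formative list was called (adjusted p = 0.375, 0.55 and 0.55).

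All 6 tested 2-cell-like genes were higher (median 3.26, adjusted p = 0.000197, p_e = 0.206), from near 0. Zscan4a went from 0.05 ± 0.09 to 1.75 ± 0.15 CPM. The p53 and senescence genes were lower in 14 of 19 cases and higher in 2 (adjusted p = 9.9e-06, p_e = 0.175). Trp53inp1 and Zmat3, targets of p53, fell by 1.39 ± 0.11 and 1.16 ± 0.09. Epithelial genes were lower in 16 of 22 cases and higher in 0 (adjusted p = 7.7e-06, p_e = 0.175), with the protease gene St14 down by 1.65 ± 0.11. Glycolysis genes were lower in 11 of 18 cases and higher in 3 (adjusted p = 0.00772, p_e = 0.637). Pfkl fell by 1.44 ± 0.19. Of 20 interferon genes 12 were lower, and 14 over the list alone (adjusted p = 0.00203, p_e = 0.608), and Bst2 (tetherin) fell by 1.40 ± 0.26.

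Il1rl1, the interleukin 33 receptor gene, was at 50.9 ± 39.2 against 0.59 ± 0.51 CPM. Ptgs2, an inducible prostaglandin synthase gene, was at 44.6 ± 23.8 against 1.95 ± 1.11 CPM, and the BMP antagonist gene Grem1 at 18.5 ± 12.8 against 0.64 ± 0.14 CPM. Of 30 fibroblast and mesenchymal genes 15 were higher and 1, Fn1, lower (adjusted p = 0.00203, p_e = 0.734). Vim was at 549 ± 194 against 196 ± 34.0 CPM and Col1a1 was not called (adjusted p = 0.428). TGF-beta and activin response genes were higher in 13 of 19 cases (adjusted p = 0.000255, p_e = 0.405). Of 19 stress genes 11 were higher (adjusted p = 0.00202, p_e = 0.222), with Fosb, an immediate-early gene, at 144 ± 70 against 10.2 ± 1.42 CPM. Xist, the RNA that silences an X chromosome in female cells, was at 37.1 ± 17.9 against 2.23 ± 1.12 CPM although the label of every library says male. The Y-linked Usp9y fell from 15.8 ± 1.87 to 0.36 ± 0.33 CPM. In all 7555 of 16132 genes changed, 3924 up and 3631 down.

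From MEF to nx2 iPSC Rbmxl2, a germ-cell RNA-binding protein gene, and Dppa4 rose from 0 counts to 130.7 ± 8.69 and 115 ± 3.52 CPM (at least 518-fold and 454-fold). Lin28a and Dppa5a, RNA-binding protein genes of pluripotent cells, rose to 372 ± 75.7 and 473 ± 92.8 CPM (log2 fold change 12.30 ± 0.29 and 12.27 ± 0.53, n = 3 and 3). Col2a1, a cartilage collagen, fell from 675 ± 31.9 to 4.25 ± 1.29 CPM. Actg2, a smooth-muscle actin, fell by 7.45 ± 0.32 and Col1a1 from 8697 ± 293 to 560 ± 278 CPM. All 19 shared pluripotency genes were higher (median 10.8, or 10.3 with genes at 0 set to their bound, adjusted p = 2.3e-10, p_e = 0.0105). Of 22 naive genes 21 were higher (adjusted p = 9.0e-09, p_e = 0.0283). Esrrb rose by 11.23 ± 0.16 and Zfp42 by 11.46 ± 0.31. Formative and primed genes were higher in 15 of 19 cases (adjusted p = 0.00281, p_e = 0.047). Nodal rose by 10.09 ± 0.34 and Sox4 fell by 2.71 ± 0.15.

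Germline genes were higher in 24 of 26 cases (median 6.45, or 5.75 with genes at 0 set to their bound, adjusted p = 3.1e-06, p_e = 0.0283), with Ddx4 (Vasa), a germ-cell helicase gene, at 27.9 ± 5.81 against 0.57 ± 0.27 CPM. All 6 tested 2-cell-like genes rose from 0 counts (adjusted p = 0.00363, p_e = 0.205), Zscan4d to 3.29 ± 1.20 CPM (at least 13-fold). Genes of DNA methylation and demethylation were higher in 14 of 16 cases (adjusted p = 2.4e-05, p_e = 0.00689). Dnmt3b rose by 5.64 ± 0.12 and Dnmt3l by 10.09 ± 0.40. Of 12 Polycomb repressive complex 2 genes 8 were higher (adjusted p = 0.00121, p_e = 0.0283), with Jarid2 up by 4.63 ± 0.08 and Suz12 by 1.66 ± 0.10. Of 30 imprinted genes 24 were lower and 4 higher (adjusted p = 0.000215, p_e = 0.205). Gnas fell by 2.64 ± 0.08 and Phlda2 rose by 5.69 ± 0.28.

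Fibroblast genes were lower in 28 of 30 cases (median -3.43, adjusted p = 2.7e-08, p_e = 0.317) and Lum, a stromal proteoglycan gene, was higher (28.6 ± 18 against 7.45 ± 1.68 CPM). All 19 TGF-beta and activin response genes were lower (adjusted p = 3.0e-07, p_e = 0.126), and Tgfb2 fell by 5.13 ± 0.29. Of 12 muscle genes 10 were lower (adjusted p = 0.00643, p_e = 0.205), and Actc1 fell by 7.24 ± 0.39. Of 14 leukocyte genes 11 were lower (adjusted p = 0.0172, p_e = 0.331), and Csf1r fell by 5.76 ± 0.37. Epithelial genes were higher in 19 of 22 cases (adjusted p = 0.000155, p_e = 0.126), with Epcam up by 7.80 ± 0.14. Of 22 cell division genes 18 were higher (adjusted p = 1.0e-05, p_e = 0.236), with Pcna up by 1.36 ± 0.06. Oxidative phosphorylation genes were higher in 18 of 25 (adjusted p = 0.00787, p_e = 0.393), with Cox5a up by 1.2 ± 0.13. Of 18 glycolysis genes 10 were higher and 4 lower (adjusted p = 0.0397, p_e = 0.612), with Slc2a3 up by 4.81 ± 0.14 and Ldha down by 1.22 ± 0.14. In all 12465 of 16132 genes changed, 6114 up and 6351 down. With library totals alone 7582 were up and 5238 down, and the median of all genes moved to 0.31 log2 units.

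**Figure D2:**
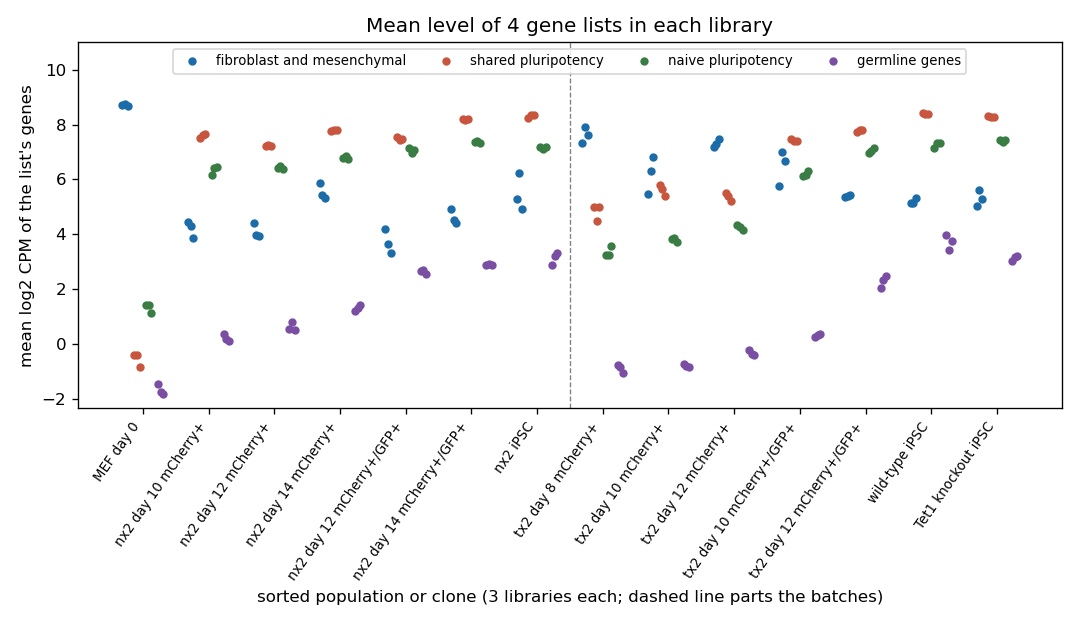
Mean log2 CPM of the genes of 4 lists (vertical axis) in each of the 3 libraries of every sorted population or clone group, a point per library, with a dashed line between the batches, which were normalised apart. The fibroblast list is highest in MEF and the pluripotency lists are lowest there.

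Between day 8 and day 12 of the mCherry+/GFP- tx2 cells Isg15, Irf7 and Ifit3, genes induced by interferon, fell from 75.9 ± 15.6, 58.8 ± 12.6 and 50 ± 14.2 CPM to 13.6 ± 3.29, 9.81 ± 2.34 and 6.65 ± 0.85 CPM (log2 fold change -2.50 ± 0.33, -2.59 ± 0.33 and -2.92 ± 0.37, n = 3 and 3). Of 20 interferon genes 16 were lower and 0 higher (median -1.54, adjusted p = 3.4e-11, p_e = 0.169). Cyp2f2, a cytochrome P450 gene of the airway, rose from 2.61 ± 0.86 to 60.0 ± 3.87 CPM. Fabp4, a fatty-acid carrier gene, rose from 2.46 ± 0.62 to 48.6 ± 18.4 CPM, and the collagenase gene Mmp13 from 10.9 ± 1.61 to 115 ± 23.9 CPM. Igfbp5, an IGF-binding protein gene, fell from 497 ± 148 to 32.7 ± 14.2 CPM and Wnt8a, a gene of the primed epiblast, from 12.6 ± 5.47 to 0.55 ± 0.32 CPM.

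Of 22 epithelial genes 18 were higher and 0 lower (median 1.68, adjusted p = 1.2e-09, p_e = 0.169). The claudin gene Cldn6 rose by 3.29 ± 0.40 and the splicing factor gene Esrp1 by 2.03 ± 0.22. Trophectoderm genes were higher in 10 of 13 cases and lower in 1 (adjusted p = 0.000143, p_e = 0.136). Krt7 rose by 3.71 ± 0.49 and Bmp8b by 3.01 ± 0.33. Endothelial genes were higher in 3 of 8 cases (adjusted p = 0.0298, p_e = 0.169), with Plvap at 41.6 ± 11.5 against 9.07 ± 3.73 CPM. Of 6 muscle genes 2 were higher (adjusted p = 0.0298, p_e = 0.169), with Des up by 3.13 ± 0.29. Of 19 stress genes 9 were higher (adjusted p = 0.00292, p_e = 0.17), with Nr4a1 up by 1.47 ± 0.13. Keratinocyte-like genes were higher in 5 of 8 cases (adjusted p = 0.0439, p_e = 0.169). Krt17 rose by 4.58 ± 0.44, and the list call was lost with the replicate block (adjusted p = 0.0597). Neural genes were lower in 7 of 10 cases (adjusted p = 0.000592, p_e = 0.169). The tau gene Mapt fell by 2.03 ± 0.16 and Map2 by 0.97 ± 0.16.

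Naive genes were higher in 12 of 22 cases (adjusted p = 0.000434, p_e = 0.169). Esrrb rose from 9.17 ± 4.15 to 85.2 ± 14.8 CPM and Zfp57, which guards imprints, by 1.31 ± 0.12. Of 19 shared pluripotency genes 9 were higher with 2 lower (adjusted p = 0.025, p_e = 0.453). Fgf4 rose by 1.54 ± 0.21. Nanog (91.2 ± 19.8 CPM at day 12) and Pou5f1 (356 ± 12.7 CPM) were not called (adjusted p = 0.969 and 0.388). Tet1 rose from 95.1 ± 11.1 to 179 ± 19 CPM. Oxidative phosphorylation genes were lower in 15 of 25 cases, and in 18 over the list alone (adjusted p = 1.5e-06, p_e = 0.169). Cox5b fell by 0.69 ± 0.09. Of 22 cell division genes 10 were lower (adjusted p = 0.000511, p_e = 0.413), with Mcm5 down by 0.71 ± 0.09. Fibroblast genes as a list were not called (3 of 30 higher, 7 lower, adjusted p = 0.195). In all 4805 of 15197 genes changed, 2601 up and 2204 down.

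At day 10 in tx2 Dnmt3l was at 35.2 ± 10.8 CPM in mCherry+/GFP+ against 0.23 ± 0.13 CPM in mCherry+/GFP- cells (log2 fold change 7.21 ± 0.36, n = 3 and 3). Foxd3, a repressor needed in pluripotent cells, was at 18.6 ± 1.00 against 0.11 ± 0.04 CPM, Tcl1 at 18.9 ± 1.71 against 0.22 ± 0.21 CPM and Dppa5a at 198 ± 30.3 against 2.71 ± 0.80 CPM. Of 19 shared pluripotency genes 18 were higher and 0 lower (median 1.63, adjusted p = 1.4e-18, p_e = 0.0073). Nanog was at 392 ± 32.2 against 111 ± 13.4 CPM, Lin28a rose by 3.65 ± 0.20 and Mycn by 2.34 ± 0.19. Pou5f1 itself rose by 0.67 ± 0.17 (adjusted p = 0.0507 without replicate 3 of the GFP- cells) and Tet1 by 0.91 ± 0.16. Naive genes were higher in 19 of 22 cases and lower in 0 (median 2.30, adjusted p = 9.7e-18, p_e = 0.00266). Prdm14, which restrains DNA methylation, rose by 4.45 ± 0.23, Dppa3 by 4.50 ± 0.31, Zfp42 from 1.16 ± 0.57 to 18.1 ± 1.73 CPM and Esrrb from 60.2 ± 18.1 to 394 ± 25.8 CPM.

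Genes of DNA methylation and demethylation were higher in 8 of 16 cases and lower in 2 (adjusted p = 0.00226, p_e = 0.14). Dnmt3b rose by 1.71 ± 0.14, Tet2 rose by 1.49 ± 0.20 and Tet3 fell by 1.04 ± 0.11. Germline genes were higher in 15 of 27 cases (median 1.97, or 0.70 with genes at 0 set to their bound, adjusted p = 0.000308, p_e = 0.221). The homeobox gene Rhox5 went from 3.75 ± 0.91 to 54.1 ± 5.37 CPM. Epithelial genes split, 9 of 22 higher and 2 lower, and 12 and 3 over the list alone (adjusted p = 0.0243, p_e = 0.703). Cldn6 rose by 2.05 ± 0.33 and the desmosome gene Dsp fell by 1.69 ± 0.19. Keratinocyte-like genes were lower in 4 of 8 cases (adjusted p = 0.00281, p_e = 0.0837), with Lgals7 down by 2.39 ± 0.22. Of 19 p53 and senescence genes 8 were lower (adjusted p = 0.000308, p_e = 0.14), with Zmat3 down by 0.43 ± 0.09. Muscle genes were higher in 4 of 6 cases (adjusted p = 0.0243, p_e = 0.14, and 0.146 without the libraries of over 8% mitochondrial reads). Mylpf was at 96.2 ± 14.1 against 9.27 ± 1.19 CPM. Among the largest falls were Dcx, a neuronal microtubule gene (-3.84 ± 0.44), and Tbx21, a T-box factor gene (-3.70 ± 0.28).

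Of 14 leukocyte genes 12 were higher in the GFP+ libraries (median 3.10, adjusted p = 2.8e-06, p_e = 0.221). Csf1r was at 8.64 ± 4.21 against 0.89 ± 0.48 CPM and C1qa, a complement gene of macrophages, at 9.23 ± 3.74 against 0.78 ± 0.59 CPM. Laptm5, of the same list, was lower (-0.68 ± 0.14). Fibroblast genes were not called (2 of 30 higher, 1 lower, adjusted p = 0.345), with Col1a1 at 1882 ± 860 against 1189 ± 585 CPM. Col1a1 was called higher with a replicate block (0.68, adjusted p = 0.0249) and without GFP+ replicate 1 or GFP- replicate 3 (0.0418 and 0.0328). In all 3398 of 15197 genes changed, 1975 up and 1423 down.

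At day 12 in tx2 Rpl10l was at 24.8 ± 3.27 CPM in mCherry+/GFP+ against 0.15 ± 0.07 CPM in mCherry+/GFP- cells (log2 fold change 7.04 ± 0.41, n = 3 and 3) and Foxd3 at 39.2 ± 1.23 against 0.33 ± 0.10 CPM. Cyct, the testis cytochrome c gene, was at 25 ± 3.15 against 0.25 ± 0.13 CPM and Zfp42 at 63.2 ± 3.14 against 1.66 ± 0.77 CPM. Of 19 shared pluripotency genes 18 were higher and 0 lower (median 2.31, adjusted p = 1.7e-10, p_e = 0.0653), with Nanog at 547 ± 23 against 91.2 ± 19.8 CPM. Of 22 naive genes 19 were higher and 2 lower (adjusted p = 6e-09, p_e = 0.0571). Esrrb was at 675 ± 27.4 CPM, Tbx3 rose by 4.66 ± 0.21 and Stat3 fell by 0.89 ± 0.10. Germline genes were higher in 23 of 27 cases and lower in 2 (median 3.81, adjusted p = 3.9e-06, p_e = 0.155). Tuba3a rose by 6.61 ± 0.40 and Brdt, a testis bromodomain gene, fell by 1.76 ± 0.37. Tet1 and Tet2 rose by 1.53 ± 0.16 and 1.96 ± 0.20, and Tet3 and Dnmt3a fell by 1.87 ± 0.12 and 1.23 ± 0.10. Of 16 DNA methylation genes 12 were higher (adjusted p = 0.00078, p_e = 0.133).

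Fibroblast and mesenchymal genes were lower in 29 of 30 cases and higher in 1 (median -2.10, adjusted p = 2.4e-08, p_e = 0.352). Vim was at 329 ± 16.8 against 1971 ± 74.6 CPM, Col1a1 at 540 ± 70.2 against 2517 ± 504 CPM and Thy1 at 56.5 ± 8.64 against 281 ± 58.6 CPM. Interferon genes were lower in 17 of 20 cases (adjusted p = 0.000834, p_e = 0.4), with Oas2 down by 1.94 ± 0.24. Of 19 TGF-beta and activin response genes 13 were lower (adjusted p = 0.00157, p_e = 0.378). Id1 fell by 2.12 ± 0.24 and Smad7 rose by 1.89 ± 0.20. Of 8 keratinocyte-like genes 6 were lower (adjusted p = 0.00862, p_e = 0.133), with Lgals7 down by 3.54 ± 0.25. The p53 and senescence genes were lower in 13 of 19 cases, and in 14 over the list alone (adjusted p = 0.00157, p_e = 0.22). The cell-cycle inhibitor gene Cdkn1a was at 118 ± 4.17 against 251 ± 26.9 CPM. Of 19 stress genes 13 were lower (adjusted p = 0.0419, p_e = 0.372, and 0.0716 without the libraries of over 8% mitochondrial reads). Hsp90aa1 rose by 1.39 ± 0.10. Of 29 imprinted genes 20 were lower and 3 higher (adjusted p = 0.000251, p_e = 0.22). Dlk1 fell by 3.42 ± 0.39 and Grb10, a growth-restraining adaptor gene, fell from 1332 ± 73.3 to 558 ± 20.6 CPM.

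Cell division genes were higher in 20 of 22 cases (adjusted p = 1.1e-06, p_e = 0.239), with Mcm3 up by 1.11 ± 0.07. Glycolysis genes were higher in 10 of 18 (adjusted p = 0.0229, p_e = 0.492), with Pfkp up by 2.15 ± 0.17 and Hk1 down by 0.42 ± 0.11. Of 25 oxidative phosphorylation genes 12 were higher (adjusted p = 0.0125, p_e = 0.378), with Cox5a up by 1.15 ± 0.14. Of 12 Polycomb repressive complex 2 genes 7 were higher, and 8 over the list alone (adjusted p = 0.0205, p_e = 0.22). Mtf2 rose by 2.04 ± 0.14. Of 22 epithelial genes 12 were higher (adjusted p = 0.0229, p_e = 0.548), with Tjp3 up by 2.49 ± 0.22 and Krt19 down by 2.39 ± 0.19. In all 9357 of 15197 genes changed, 4742 up and 4615 down.

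Between day 10 and day 12 Sohlh2 went in the mCherry+/GFP+ tx2 cells from 0.17 ± 0.07 to 10.6 ± 2.51 CPM (log2 fold change 5.84 ± 0.36, n = 3 and 3). Dazl went from 0.92 ± 0.30 to 14.3 ± 0.81 CPM and Lncenc1 from 11.5 ± 1.58 to 120 ± 9.84 CPM. Of 27 germline genes 19 were higher and 0 lower, and 21 and 0 over the list alone (median 2.52, adjusted p = 6.3e-12, p_e = 0.0368). Mov10l1, a piRNA factor gene, rose by 3.51 ± 0.35 and Stag3 rose from 5.70 ± 1.40 to 37.5 ± 7.57 CPM. Naive genes were higher in 14 of 22 cases and lower in 1 (adjusted p = 2.5e-10, p_e = 0.0297). Tcl1 went from 18.9 ± 1.71 to 70.8 ± 12.3 CPM and Tfcp2l1 from 275 ± 20.4 to 570 ± 27.3 CPM. Shared pluripotency genes followed in 7 of 19 cases (adjusted p = 0.00261, p_e = 0.306). Dppa4 rose by 0.96 ± 0.18 and Nanog by 0.48 ± 0.14 (adjusted p = 0.0948 without replicate 2 of the day 10 GFP+ cells), while Pou5f1 was not called (-0.11 ± 0.16, adjusted p = 0.691). Tet1 and Tet2 were not called (0.23 ± 0.16 and 0.31 ± 0.19, adjusted p = 0.302 and 0.253), though Tet2 was with only the groups of the contrast (0.0167). Tet3 and Dnmt3a fell by 0.79 ± 0.12 and 0.55 ± 0.10.

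Fibroblast genes were lower in 22 of 30 cases and Fn1 alone higher, and 25 and 2 over the list alone (median -1.39, adjusted p = 5.4e-08, p_e = 0.405). Col1a1 went from 1882 ± 860 to 540 ± 70.2 CPM, Postn, a matrix gene, from 243 ± 120 to 56.9 ± 1.52 CPM and Igfbp5 from 134 ± 77.2 to 13.9 ± 4.79 CPM. Interferon genes were lower in 16 of 20 cases (adjusted p = 5.4e-08, p_e = 0.297), with Isg15 from 17.9 ± 7.04 to 3.54 ± 0.93 CPM. Leukocyte genes were lower in 10 of 14 cases, and in 12 over the list alone (median -1.51, adjusted p = 0.000101, p_e = 0.298). Csf1r went from 8.64 ± 4.21 to 2.72 ± 1.73 CPM (adjusted p = 0.0523 with only the groups of the contrast). Of 29 imprinted genes 13 were lower (adjusted p = 0.00102, p_e = 0.28). Dlk1 fell by 3.13 ± 0.39 and Cdkn1c fell from 131 ± 72.4 to 26.9 ± 4.05 CPM. TGF-beta and activin response genes were lower in 7 of 19 cases (adjusted p = 0.00204, p_e = 0.419), with Ltbp1 down by 1.39 ± 0.16. Of 19 p53 and senescence genes 6 were lower (adjusted p = 0.00284, p_e = 0.28), with Cdkn1a down by 0.53 ± 0.12. Of 8 keratinocyte-like genes 4 were lower (adjusted p = 0.00525, p_e = 0.145), with Itgb4 down by 0.90 ± 0.15. Trh fell from 368 ± 37.8 to 49.4 ± 12.6 CPM.

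Trophectoderm genes were higher in 6 of 13 cases and lower in 1 (adjusted p = 0.0241, p_e = 0.28). Gata3 rose by 1.84 ± 0.36 from under 1 CPM and Tfap2a fell by 0.75 ± 0.16. Epithelial genes were higher in 5 of 22 cases (adjusted p = 0.00204, p_e = 0.501), with Grhl2 up by 0.99 ± 0.23. Of 6 muscle genes 2 were higher (adjusted p = 0.0157, p_e = 0.145), with Des from 4.75 ± 1.21 to 12.8 ± 1.33 CPM. Of 12 Polycomb genes 3 were higher, or 6 over the list alone (adjusted p = 0.00367, p_e = 0.145), with Suz12 up by 0.52 ± 0.12. In all 3818 of 15197 genes changed, 1851 up and 1967 down. Without replicate 2 of the day 10 GFP+ cells the count was 2107.

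**Figure D3:**
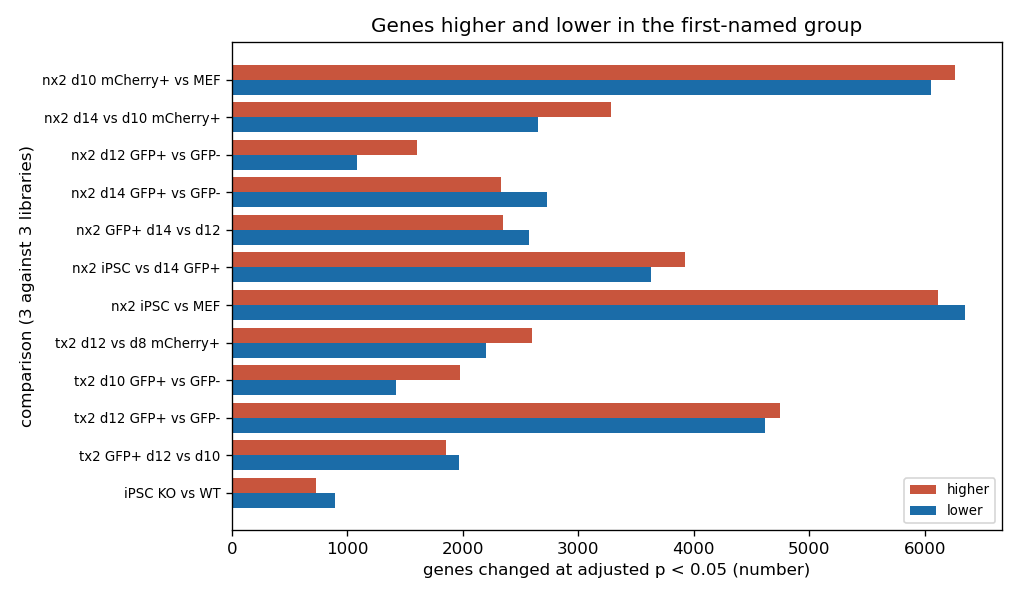
Number of genes higher and lower in the first-named group at adjusted p < 0.05 (horizontal bars) in each of 12 comparisons of 3 against 3 libraries. The bars run from 727 higher and 892 lower genes in knockout against wild-type iPSC to 6114 higher and 6351 lower in nx2 iPSC against MEF.

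The nx2 effect of GFP sorting kept its genes from day 12 to day 14. Of all tested genes 1246 were higher on both days against 231 expected by chance, and 857 were lower on both against 182. Only 13 of 2116 genes called on both days pointed in opposite directions. The effects correlated over 16132 genes, not independent replicates (Pearson r = 0.684). A change was called in 249 of them (111 higher at day 14, 138 lower), which leaves the rest open. Trh gained 2.94 ± 0.30 (n = 3 in each of 4 groups). Krt8 and Krt18 changed by -1.56 ± 0.33 and -1.17 ± 0.29, Rhox9 by -1.85 ± 0.30 and Airn, the antisense transcript at Igf2r, by -1.70 ± 0.24.

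By list, glycolysis genes gained at day 14 (2 of 18 called, 6 and 1 against over the list alone, adjusted p = 4.8e-07, p_e = 0.231). Hk2, a hexokinase gene, changed by 0.45 ± 0.11 and Pfkp by 0.93 ± 0.22. Imprinted genes lost in 5 of 30 cases (adjusted p = 0.000109, p_e = 0.231), with Igf2r at -0.65 ± 0.11 and Slc38a4 at -0.72 ± 0.12. Epithelial genes lost in 4 of 22 with Spint1 against them (adjusted p = 0.00183, p_e = 0.231). Germline genes lost in 2 of 26, or 4 over the list alone (adjusted p = 0.00648, p_e = 0.231), with Rhox5 at -1.36 ± 0.30. Of shared pluripotency genes Utf1 gained 0.52 ± 0.13 and 18 were not called. On the list 5 gained and 2 lost over the list alone (adjusted p = 0.00404, p_e = 0.231). Some lists passed the list test with 0 called members, and not with an estimated correlation. Their medians were -0.65 for fibroblast (adjusted p = 0.00491, p_e = 0.657), 0.14 for cell division (adjusted p = 3.7e-05, p_e = 0.264) and 0.07 for oxidative phosphorylation genes (adjusted p = 0.0349, p_e = 0.567). Tet1, Tet2, Pou5f1, Nanog and Esrrb were not called (adjusted p = 0.626, 0.854, 0.637, 0.85 and 0.97), though Pou5f1 was with only the groups of the contrast (0.0455). None of Krt8, Krt18, Hk2, Pfkp, Rhox5 and Utf1 kept its call with every library left out in turn. With only the groups of the contrast in the fit 928 genes were called and with DESeq2 412. Without the libraries of over 8% mitochondrial reads 396 were called, and leaving out replicate 3 of the day 12 mCherry+ cells 117.

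In tx2, between day 10 and day 12, 1656 genes were higher on both days against 616 expected by chance and 1247 were lower on both against 432. Of 2989 called on both days 86 pointed in opposite directions, and across 15197 genes r was 0.68. The effect changed for 4143 of 15197 genes, 1603 higher at day 12 and 2540 lower. In what follows lower means an effect lower at day 12. Fibroblast genes were lower in 28 of 30 cases (median -2.30, adjusted p = 5.9e-15, p_e = 0.245). Col1a1 changed by -2.88 ± 0.47, Fbn1, a microfibril gene, by -2.32 ± 0.37 and Mmp13 by -3.73 ± 0.42. Interferon genes were lower in 17 of 20 (adjusted p = 1.1e-07, p_e = 0.245), with Ifit2 at -2.35 ± 0.46. Of 19 TGF-beta and activin response genes 14 were lower (adjusted p = 5e-06, p_e = 0.245), with Tgfbr2 at -2.28 ± 0.43. Of 14 leukocyte genes 9 were lower (adjusted p = 0.000604, p_e = 0.261), with Lyz2 at -2.65 ± 0.70. Of 29 imprinted genes 13 were lower (adjusted p = 0.00033, p_e = 0.245), with Mest at -1.58 ± 0.24. Of 12 endoderm genes 7 were lower with Hnf4a against them (adjusted p = 0.00551, p_e = 0.245). Col4a1 changed by -1.96 ± 0.28 and Cubn by -3.70 ± 0.60. Of 8 keratinocyte-like genes 3 were lower (adjusted p = 0.0233, p_e = 0.245), with Krtdap at -2.31 ± 0.51.

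Cell division genes were higher in 15 of 22 cases (adjusted p = 2.6e-09, p_e = 0.245), with Mcm5 at 0.84 ± 0.13. Of 12 Polycomb genes 7 were higher (adjusted p = 0.00301, p_e = 0.245), with Mtf2 at 1.00 ± 0.19. Of 25 oxidative phosphorylation genes 6 were higher (adjusted p = 0.000213, p_e = 0.245), with Ndufb5 at 0.62 ± 0.13. Of 18 glycolysis genes 4 were higher (adjusted p = 0.00551, p_e = 0.414), with Hk2 at 0.92 ± 0.14. Shared pluripotency genes were higher in 7 of 19 cases, or 9 over the list alone (adjusted p = 0.000354, p_e = 0.245). Sall4 changed by 0.86 ± 0.19 and Nanog by 0.76 ± 0.20. Of 27 germline genes 5 were higher (adjusted p = 0.00455, p_e = 0.28), with Stag3 at 2.06 ± 0.29. Of 16 DNA methylation genes 7 were higher (adjusted p = 0.0233, p_e = 0.245). Uhrf1, which guides maintenance methylation, changed by 0.83 ± 0.15, Tet1 by 0.62 ± 0.22 and Tet3 by -0.83 ± 0.16. The Tet1 call was lost when any of 9 libraries was left out (adjusted p up to 0.139) and without the low-count filter (0.0556).

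At day 12 the tx2 effect of GFP on Dppa3 exceeded that in nx2 by 5.29 ± 0.32 (log2, n = 3 in each of 4 groups). The effect on Dnmt3l exceeded it by 4.85 ± 0.37, that on Prdm14 by 4.53 ± 0.25 and that on Zfp42 by 3.22 ± 0.26. Shared pluripotency genes were higher in 17 of 19 cases and lower in 0 (median 2.02, adjusted p = 2.6e-18, p_e = 0.00121). Lin28a differed by 3.45 ± 0.24 and Nanog by 2.48 ± 0.18. Naive genes were higher in 17 of 22 cases and lower in 1 (median 2.33, adjusted p = 2.6e-12, p_e = 0.00166). Mybl2 differed by 2.33 ± 0.13, Esrrb by 2.75 ± 0.24 and Stat3 by -0.73 ± 0.11. DNA methylation genes were higher in 11 of 16 cases and lower in 2 (adjusted p = 5.1e-05, p_e = 0.016). Dnmt3b differed by 2.52 ± 0.18, Tet2 by 1.51 ± 0.23, Tet1 by 1.49 ± 0.21 and Tet3 by -2.14 ± 0.17. The difference for Pou5f1 was not called (0.42 ± 0.22, adjusted p = 0.122), but was with only the groups of the contrast (0.000355) and without the libraries of over 8% mitochondrial reads (0.0164).

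Cell division genes were higher in 21 of 22 cases (adjusted p = 9.5e-12, p_e = 0.113), with Rrm2, a ribonucleotide reductase gene, at 0.94 ± 0.11. Of 22 epithelial genes 12 were higher, or 15 over the list alone (adjusted p = 2e-05, p_e = 0.308). Rab25 differed by 2.29 ± 0.34 and Krt19 by -1.46 ± 0.35. Of 27 germline genes 11 were higher (adjusted p = 0.0328, p_e = 0.412, and 0.0544 without the libraries of over 8% mitochondrial reads). Dpep3 differed by 4.39 ± 0.84 and Sycp2 by -3.08 ± 0.87. Oxidative phosphorylation genes were higher in 8 of 25 (adjusted p = 0.00754, p_e = 0.412), with Cox7a2 at 0.54 ± 0.15. Of 18 glycolysis genes 9 were higher (adjusted p = 0.0132, p_e = 0.469), with Slc2a3 at 1.58 ± 0.23. Of 12 Polycomb genes 5 were higher (adjusted p = 0.0132, p_e = 0.171), with Ezh2 at 1.15 ± 0.16.

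Fibroblast genes were lower in 21 of 30 cases, or 23 over the list alone (median -1.64, adjusted p = 4e-06, p_e = 0.418). Twist1 differed by -2.65 ± 0.46 and Vim by -2.27 ± 0.30. Of 19 p53 and senescence genes 10 were lower (adjusted p = 0.00884, p_e = 0.308), with Ccng1 at -0.85 ± 0.20. Of 20 interferon genes 7 were lower (adjusted p = 0.0132, p_e = 0.48), with Usp18 at -2.17 ± 0.66. Of 11 keratinocyte-like genes 5 were lower (adjusted p = 0.0278, p_e = 0.308), with Itgb4 at -1.99 ± 0.19. Of 19 TGF-beta and activin response genes 8 were lower (adjusted p = 0.0278, p_e = 0.469, and 0.0581 without the libraries of over 8% mitochondrial reads). Tgfbi differed by -2.30 ± 0.47. Of 30 imprinted genes 11 were lower and 4 higher (adjusted p = 0.0304, p_e = 0.418), with Igf2r at -1.15 ± 0.20 and Phlda2 at 3.52 ± 0.30. Ina, a neuronal intermediate filament gene, had the best supported of the largest rises (5.65 ± 0.38). In all 6371 of 16652 genes differed, 3274 higher in tx2 and 3097 lower. In GFP+ cells of both systems 1091 genes were higher against 473 expected by chance and 249 of 2001 called in both pointed in opposite directions (r = 0.566 across 14855 genes, not independent replicates). Reporter system, mouse line and sequencing batch changed together here, and so did the labelled stage, I in tx2 and III in nx2 for GFP- cells and III and IV for GFP+ cells.

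The labels give stage III to GFP- nx2 cells and to GFP+ tx2 cells of day 12. These were compared through the iPSC of each batch. A value is the distance of tx2 cells from wild-type iPSC minus that of nx2 cells from nx2 iPSC, and a difference between the iPSC enters it too. Serpina3n, a secreted protease inhibitor gene, differed by 7.53 ± 0.83 (log2, n = 3 in each of 4 groups; 43.3 ± 9.36 CPM in tx2 cells and 0.74 ± 0.15 CPM in wild-type iPSC). Cyp2f2 differed by 6.86 ± 0.72 (15.2 ± 1.81 and 0.28 ± 0.23 CPM) and Eno1b, a retrocopy of an enolase gene, by -6.45 ± 0.66 (0.99 ± 0.43 and 88.0 ± 11.5 CPM). Fibroblast genes were higher in 21 of 30 cases and lower in 0, or 25 and 0 over the list alone (median 1.77, adjusted p = 4.5e-08, p_e = 0.348). Mmp2 differed by 2.78 ± 0.46 and Fbn1 by 2.05 ± 0.43, and Col1a1 was not called (0.95 ± 0.51, adjusted p = 0.179). Formative and primed genes were higher in 10 of 19 cases, or 12 over the list alone (median 0.92, adjusted p = 4.6e-05, p_e = 0.0511). Otx2, a driver of the formative state, differed by 4.75 ± 0.57, Lef1 by 5.34 ± 0.68 and Lefty2, a Nodal antagonist gene, by 2.80 ± 0.45. Endoderm genes were higher in 10 of 13 cases (median 1.54, adjusted p = 4.6e-05, p_e = 0.0601). Pdgfra differed by 2.79 ± 0.51 and Gata4 by 2.59 ± 0.61.

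Glycolysis genes were higher in 9 of 18 cases and lower in 1 (adjusted p = 4.6e-05, p_e = 0.348), with Slc2a1 at 1.41 ± 0.20. Of 27 germline genes 11 were higher, or 13 over the list alone (median 1.04, adjusted p = 0.000266, p_e = 0.209). Rpl10l differed by 4.86 ± 0.45 and Mael by 3.45 ± 0.51. Of 19 TGF-beta and activin response genes 11 were higher with Id2 lower (adjusted p = 0.000456, p_e = 0.348). Thbs1 differed by 4.26 ± 0.64 and Bmp4 by 2.15 ± 0.37. Shared pluripotency genes were higher in 7 of 19 cases, or 9 over the list alone (adjusted p = 0.000723, p_e = 0.277). Lin28a differed by 1.32 ± 0.21. Of 22 naive genes 4 were higher and 1 lower (adjusted p = 0.0202, p_e = 0.348), with Gbx2 at 3.19 ± 0.46 and Tbx3 at 1.60 ± 0.20. Nanog (-0.07 ± 0.18), Esrrb (0.02 ± 0.23), Tet1 (-0.13 ± 0.21) and Tet2 (0.16 ± 0.22) were not called (adjusted p = 0.82, 0.974, 0.709 and 0.663). Without wild-type replicate 1 Tet2 was higher by 0.56 (adjusted p = 0.00957). Tet3 and Dnmt3l were higher by 1.43 ± 0.18 and 2.23 ± 0.29. Leukocyte genes were higher in 9 of 15 cases with Cd68 lower (adjusted p = 0.0181, p_e = 0.528, and 0.0532 without the libraries of over 8% mitochondrial reads). C1qa differed by 6.21 ± 1.59. Of 10 endothelial genes 3 were higher (adjusted p = 0.0381, p_e = 0.229). Flt1 differed by 3.21 ± 0.68, and the list call was lost with a replicate block (0.144) and with genes of at least 1 CPM (0.056). Cell division genes were lower in 8 of 22 cases (adjusted p = 0.000356, p_e = 0.375). Mki67 differed by -0.99 ± 0.28 (-0.54 and adjusted p = 0.0908 without wild-type replicate 1). In all 3995 of 16652 genes differed, 2189 higher and 1806 lower. Library totals as the only scaling moved the median of all genes to 0.116 and the split to 2549 higher and 1200 lower, and with only the 4 groups in the fit 1927 genes were called.

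Beside Tet1, Lef1 was at 30.4 ± 2.62 CPM in knockout and 3.36 ± 1.95 CPM in wild-type iPSC clones (log2 fold change 3.26 ± 0.33, n = 3 and 3). The imprinted Grb10 was at 371 ± 21.8 against 68.7 ± 16.1 CPM (2.44 ± 0.12). Obsl1, a cytoskeletal adaptor gene, was at 169 ± 5.77 against 25.5 ± 9.20 CPM and Slc4a3, an anion exchanger gene, at 35.3 ± 3.79 against 3.90 ± 1.67 CPM. Capn11, a testis calpain gene, went down to 1.29 ± 0.43 from 15.1 ± 2.98 CPM (-3.56 ± 0.28), and Mmrn2, an endothelial matrix gene, to 2.42 ± 0.66 from 21.2 ± 1.93 CPM. Ccnb1ip1, a meiotic crossover gene, went down to 3.08 ± 0.30 from 17.9 ± 0.82 CPM and Mpi, a mannose metabolism gene, to 2.29 ± 0.96 from 11.9 ± 2.34 CPM.

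Formative and primed genes were higher in 10 of 18 cases and lower in 0 (median 0.55, adjusted p = 1.3e-05, p_e = 0.106). Sall2 rose by 1.28 ± 0.16, Dnmt3b from 314 ± 23.2 to 482 ± 5.71 CPM and Dnmt3a from 221 ± 20.9 to 285 ± 11.9 CPM. The Dnmt3a call was lost when any of 3 clones was left out (adjusted p up to 0.074). With only the groups of the contrast Dnmt3a, Bbc3 and Dazl were not called (0.142, 0.0695 and 0.088). Dnmt3l, a cofactor of both methyltransferases, rose by 0.81 ± 0.18 and Dppa3 by 1.32 ± 0.26. The p53 and senescence genes were higher in 6 of 19 cases, or 10 over the list alone (adjusted p = 0.000138, p_e = 0.227). The pro-apoptotic genes Pmaip1 and Bbc3 rose by 1.31 ± 0.12 and 1.02 ± 0.16 and Zmat3 by 0.61 ± 0.09. Of 11 tested 2-cell-like genes 10 were lower, and 11 over the list alone (median -2.30, adjusted p = 6.5e-11, p_e = 0.227). Zscan4d, which marks a 2-cell-like state, was at 2.59 ± 0.99 against 12.6 ± 5.01 CPM. Germline genes were lower in 9 of 27 cases (median -0.67, adjusted p = 3.8e-05, p_e = 0.262). Ddx4 fell by 1.22 ± 0.23, Dazl by 1.35 ± 0.26 and Stag3 by 0.73 ± 0.15.

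Pou5f1, Nanog, Esrrb, Zfp42 and Cdh1 were not called (adjusted p = 0.25, 0.418, 0.428, 0.622 and 0.963), though Pou5f1 was without wild-type replicate 2 (0.51, adjusted p = 0.0449). Neither naive (3 of 22 higher, 1 lower, adjusted p = 0.358) nor shared pluripotency genes (2 of 19 higher, 1 lower, adjusted p = 0.653) were called. Imprinted genes were not called as a list (5 of 29 lower, 2 higher, adjusted p = 0.4). Glycolysis genes were higher in 2 of 18 cases (adjusted p = 0.0202, p_e = 0.9). Ldha rose by 0.77 ± 0.14 and Hk1 fell by 0.53 ± 0.11, and the list was not called without the libraries of over 8% mitochondrial reads (adjusted p = 0.407). Mitochondrially encoded genes were lower in 6 of 8 cases (adjusted p = 0.00442, p_e = 0.9). Wild-type replicate 1 stood apart with 12.2% of its counts from them, but this list call held when it was left out. In all 1619 of 15197 genes changed, 727 up and 892 down. The count depended on single clones, with 887, 882 and 832 without knockout replicates 1, 2 and 3 and 2581 without wild-type replicate 2. It was 448 with only the groups of the contrast in the fit. Library totals as the only scaling turned the split to 760 up and 598 down.

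**Figure D4:**
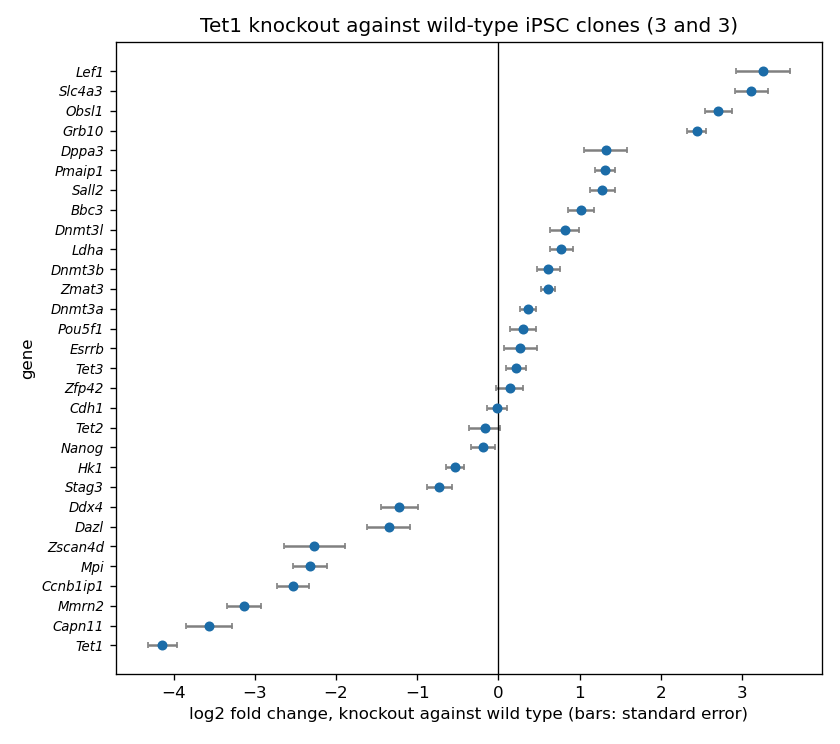
Log2 fold changes of named genes in knockout against wild-type iPSC (3 and 3 clones), a point per gene with bars of 1 standard error. Tet1 lies lowest at -4.14 and Lef1 highest at 3.26.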

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

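The test of genes nested inside another gene was chosen after the zeros were seen, and all others here were planned.

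Fibroblast genes were higher late (p_e = 0.344 and 0.734), in day 14 mCherry+/GFP- nx2 cells against day 10 and in nx2 iPSC against day 14 mCherry+/GFP+ cells. They were also higher in nx2 mCherry+/GFP+ cells at day 14 than at day 12 (p_e = 0.504), where no share was computed. The day 14 cells were sorted for mCherry and MEF held Tet1 at only 10.3 ± 1.59 CPM, so the gate should remove MEF. If MEF-like cells were mixed in, all genes abundant in MEF should imply the same share of them. Over 100 genes at least 16-fold higher in MEF the median implied share at day 14 was 2.20% (quartiles 1.29 and 4.61%), with 70% of genes within 3-fold of it (95% interval 60.0 to 78.8), right at the bound set for this test. Of the 100 genes 8 implied a share over 10-fold below the median, 6 of them at or below 0. Inhba implied 0.082% and Col1a1 13.6%, so 1 share of MEF does not account for every gene. For iPSC, with MEF standing in for feeders, the median share was 3.72% (2.22 and 5.05%), with 82% of genes within 3-fold (73.1 to 89.0). Of these genes 5 were over 10-fold below the median, 3 of them at or below 0. Feeder carry-over could account for most listed genes. Here Col11a1 implied -2.41% and Ccnd1 31.4%, so 1 share does not account for every gene either. Col1a1, under 16-fold higher in MEF and so not listed, had no higher mean in iPSC. Re-expression of a fibroblast programme by the reprogramming cells was not tested and stays open for both.

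Leukocyte genes were higher in day 10 mCherry+/GFP+ than in mCherry+/GFP- tx2 cells (p_e = 0.221). A shift of all low-count genes is argued against by 1217 genes of matched abundance, whose median log2 fold change was 0.106 against 3.10 for the leukocyte list. Of 19 tested genes of a further macrophage list 15 were higher and 0 lower (78.9%, median 2.80), as macrophages in the sorted gate would give. Lyz2 was uneven between lines, at 29.5, 99.7 and 107 CPM in GFP+ and 3.3, 15.2 and 9.1 CPM in GFP- cells. Whether such cells were sorted through the fluorescence gate or arose in the culture was not tested.

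Sox2 was at 0 counts in all 42 libraries, pluripotent cells included. Its span (chromosome 3, 34650405 to 34652461) lies inside Sox2ot on the same strand (34104270 to 34682619). All 408 protein-coding names wholly inside a same-strand gene were at 0 (100%), which the rule that drops reads in more than 1 gene would give. Of 655 names wholly covered on the opposite strand only, 107 were at 0 (16.3%), which argues against absent transcription as the reason for the whole set. The same holds for Cox4i1, Tubb3, Neurod1, Foxf1, Sox1, Mkrn3 and Mcts2, so nothing is said of these genes here.

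Effects differed between groups by the test of the difference in 249 genes for GFP in nx2 between days, 4143 for GFP in tx2 between days, 6371 for GFP between systems at day 12 and 3995 for stage III. Among 21 draws of the libraries, the real one included, 3 gave as many genes in the nx2 case (highest other 2185) and 2 in each of the rest (6339, 7607 and 4848). The other draws that reached the real count keep 1 arm whole, so its effect enters the difference. Draws that mix both arms gave at most 0, 0, 0 and 1 genes, since mixed groups widen the spread. Neither bears on chance.

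The 12 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. Only the real one gave as many genes, but the others mix groups, which widens the spread. The real counts are given above. The highest other was 1 for nx2 day 10 against MEF and for tx2 day 12 against 8. It was 496 for GFP in tx2 at day 10 and 0 in all other cases. Among the 3 other splits that part as many line pairs the highest was 1, at tx2 day 12 against 8.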

How the results depend on the processing

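The setting without the libraries of over 8% mitochondrial reads was chosen after the data were seen. Of 413 calls of named genes, 5 were left out of the text as not holding. Under some setting 17 were lost, 18 when 1 library was left out, and 0 changed direction. Tet1 in the knockout stayed between -4.25 and -3.90. Of the 16 counts of changed genes 3 moved by over 1.5 times under another setting. With only the groups of the contrast in the fit, which leaves fewer libraries for the dispersion, the knockout count went from 1619 to 448, nx2 GFP between days from 249 to 928 and stage III from 3995 to 1927. The nx2 count was 412 with DESeq2 and 396 without the high mitochondrial libraries, and the cause was not tested. Leaving out 1 library gave 832 to 2581 genes for the knockout, 117 to 171 for nx2 GFP between days (over 1.5 times fewer for 8 of 12 libraries) and 2107 to 3946 for tx2 GFP+ day 12 against 10.

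Of 185 list calls 20 held with an estimated correlation, which widens the test when members vary together between replicates. These were 2 of 15 for nx2 day 10 against MEF, 0 of 9 for day 14 against 10, 1 of 7 for GFP at day 12, 2 of 12 at day 14, 2 of 12 for GFP+ day 14 against 12, 0 of 8 for iPSC against day 14 and 6 of 16 against MEF. In tx2 they were 0 of 12 for day 12 against 8, 2 of 9 for GFP at day 10, 0 of 16 at day 12 and 2 of 14 for GFP+ day 12 against 10. They were 0 of 6 for the knockout, 0 of 9 and 0 of 14 for GFP between days in nx2 and tx2, 3 of 15 for GFP between systems and 0 of 11 for stage III. RLE kept 183 of the 185, the stricter filter 179, and leaving out the high mitochondrial libraries 173.

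The replicate block gave 2840 genes for GFP in nx2 at day 12. Clone numbers in the batch 2 iPSC do not pair libraries (0 of 3 correlations over 0.1), and with them as block the knockout count was 2184. In the blocked fit Pfkp lost its call (adjusted p = 0.0529) in nx2 GFP between days, Col1a1 became called (0.0249) for GFP in tx2 at day 10, and the 2 list calls named in the text were lost. It ended no other call of a named gene or list, and added list calls for fibroblast genes (0.0317) in nx2 GFP at day 12, epithelial genes (0.0385) in nx2 GFP+ day 14 against 12, imprinted and interferon genes (0.0324 and 0.0446) in tx2 GFP at day 10, glycolysis (0.0398) in tx2 GFP+ day 12 against 10, and 2-cell-like, imprinted and mitochondrially encoded genes (0.00165, 0.0346 and 0.0012) in stage III. The correlation of nx2 GFP effects between days, 0.684, was 0.735 with genes of at least 1 CPM and 0.806 with genes called in either. Mean list levels moved by over 1 SD in 13 and 15 of 56 cases with prior counts of 0.5 and 5, as low counts are pulled more. Depth limits what the traces can show, since in the shallowest library 3 counts are 0.444 CPM.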

Other observations

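All values in this part were chosen after the results were seen.

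In nx2 Myc went from 147 ± 1.87 CPM in MEF to 448 ± 27.5 CPM at day 10, 242 ± 28.7 and 305 ± 50.1 CPM in GFP- and GFP+ cells at day 12 and 10.2 ± 1.82 and 7.90 ± 1.48 CPM at day 14. In tx2, which has no day 14, Myc was at 571 ± 17.7 CPM at day 8 and at 554 ± 17.2 and 345 ± 26.6 CPM in GFP- and GFP+ cells at day 12, against 38.7 ± 2.21 CPM in wild-type iPSC. Klf4 was at 440 ± 19.4 CPM in day 14 GFP+ nx2 cells and at 554 ± 28.4 CPM in day 12 GFP+ tx2 cells. These counts per gene name do not part endogenous Myc and Klf4 transcripts from those of any delivered factors.

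The Y-linked genes were low in replicate 3 of the nx2 iPSC. Ddx3y was at 101, 122 and 11.4 CPM in replicates 1, 2 and 3, Eif2s3y at 89.6, 74.9 and 9.31 CPM, Kdm5d at 35.9, 30.8 and 2.55 CPM and Uty at 41.1, 47.0 and 3.97 CPM. In wild-type replicate 2 Ddx3y was at 60.1 CPM against 107 and 110 CPM in the other clones, and Eif2s3y at 41.9 against 72.3 and 70.3 CPM. Xist, near 0 in MEF (0.152 CPM), was at 33.5 ± 7.99 and 25.5 ± 9 CPM in wild-type and knockout iPSC and at 36.5 ± 13.1 CPM in tx2 cells of day 8.

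Wild-type iPSC replicate 1 had the highest mitochondrial share, 12.18%, the lowest scaling factor, 0.7818, and 1.95% of its counts on Pprc1.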
